A study of Arabidopsis thaliana with 4 samples.

How the data were processed

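ChIP-seq with an antibody against FLAG was done on developing seeds of lec1-4 plants carrying LEC1-FLAG under the LEC1 promoter, with 2 ChIP and 2 input libraries. The series design calls the replicates biological. Fragments of 150 to 200 bp were preferred in library preparation, per the labels' protocols. The submitters' processing notes name BWA 0.7.12, MACS2 2.1.0.20150420 and the genome build TAIR10. The alignment file names in the headers point to reads that mapped to 1 place, with duplicates removed. Per the headers, MACS 2.1.0.20150420 called peaks in each ChIP library over its own input library, so replicates were never pooled. The headers number the libraries 3 and 4, and the deposited sample labels, followed here, call them replicates 1 and 2. The headers give a q threshold of 0.05, no model of fragment shift, a fragment extension of 187 bp in replicate 1 and 149 bp in replicate 2, at most 1 tag per position and strand, a search for several summits per peak, and scaling of the larger library down to the smaller. Tag sizes were 50 and 49 bp. The input libraries entered this work through those peak calls, and files of their own were not analysed here.

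Each list gives a position, a pileup, a fold and significance values per summit. The pileup deposited by the authors is a signal, the number of extended ChIP fragments over the summit. The fold enrichment deposited by the authors is a ratio of that pileup to the local background that MACS took from the input, with 1 added to both. The −log10 p-value and −log10 q-value deposited by the authors state the significance of that ratio. These values are the authors' own for each peak. They were used to describe, rank and filter peaks, and values set side by side across the replicates come from separate calls with different extensions and input depths. The local background was computed back as (pileup + 1) / fold, so each value given includes the added 1, which draws ratios of backgrounds towards 1. Replicate 1 used 4454133 of 4455659 ChIP tags and replicate 2 used 4493099 of 4495030, so the depth of the ChIP libraries differed little, while input depth was 7578894 and 9646586 tags.

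Lines with the same start and end were joined into 1 peak, represented by its summit of highest fold. Peaks on the 5 nuclear chromosomes entered the comparisons, and 26 chloroplast peaks of replicate 2 were kept apart. A replicate 1 and a replicate 2 peak were shared where they overlapped by at least 50% of the shorter one. The overlap was computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and bedtools 2.31.1 gave the same 3125 and 3182 peaks. Chance was measured with 1000 placements of the replicate 2 peaks on the stretch of each chromosome between the first and the last peak, since chromosome lengths were not used here. Correlations had permutation tests with 100000 resamples in scipy 1.17.1. Intervals are 95%, by Wilson's method for shares of peaks, exact binomial for shares of lists and exact Poisson for pileups, and cover counting error only. Those printed beside folds take the local background as exact, so counting error of the input is left out.

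Genes came from a RefSeq gene table of assembly TAIR10.1, used for names and for which genes neighbour a peak. As a check of the coordinates, summits were shifted against the genes, and the share within 200 bp of a gene end was highest with no shift on each of the 5 chromosomes. The design fixed before the data were examined used the transcription start on its strand, exons, introns and untranslated regions. Strand and exon structure were not available in that table, so the window ran from 1000 bp outside to 200 bp inside either end of a gene, and positions were classed as within 1000 bp outside a gene, gene interior, other gene type or intergenic. A target gene had a summit in this window in both replicates. The planned search for sequence elements needs a genome sequence and was not done here. All 331 genes of the 17 lists matched the table by identifier. Lists were tested with two-sided Fisher's exact tests against all other protein-coding nuclear genes, with Benjamini-Hochberg adjustment over the 17 lists.

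Genes were named by a rule fixed before the data were examined. It took LEC1, L1L, ABI3, FUS3, LEC2, WRI1, ABI5 and bZIP67 whatever their values, the 10 target genes with the highest smaller fold of both replicates, up to 3 such genes per list, and 3 genes met in replicate 1 alone and 3 in replicate 2 alone, with no peak of the other replicate within 1000 bp. MYB118, DOG1, CRD, NF-YA2, AT4G32272, HY5, SOC1, FLC and the genes of the closing section that are outside this rule were chosen after their values were seen. Genes without a symbol are given by identifier.

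The scripts were tested on simulated data. All 1000 peaks planted on replicate 1 peaks among 3361 were counted as shared, and all 1850 simulated summits around the ends of 370 isolated genes were assigned as placed. With 500 random sets of target genes among 27444, 1.60% of the sets gave any list call. In a further test each gene of the desiccation list was met with a probability of 50%, so the number met varied between sets. The list was called in 81.8% of 500 such sets. Alternatives changed the overlap rule, the peak threshold, the gene window, the random placement, the comparison lists and the replicates used. Figures were drawn with matplotlib 3.10.9.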

Results

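The series mapped where LEC1, the seed-expressed NF-YB subunit that is a central regulator of embryo maturation, sits on the genome of developing Arabidopsis thaliana seeds. The plants were lec1-4 mutants that carried FLAG-tagged LEC1 driven by the LEC1 promoter, and chromatin was precipitated with an antibody against FLAG. The sample labels place the seeds at a mature stage, while the series title speaks of embryo expansion. Plants grew at 22°C with 16 h of light and 8 h of dark. There were 2 biological replicates of the ChIP and 2 of the matching input chromatin, and each replicate had 1 list of peaks, called by the authors for its ChIP library over its input library. The samples held no FLAG precipitation from plants without the tag. Binding by LEC1-FLAG was therefore not separated from background of the antibody, at single genes or in the gene lists. Replicate 1 rested on 4454133 ChIP tags and 7578894 input tags, and replicate 2 on 4493099 ChIP tags and 9646586 input tags. On the 5 nuclear chromosomes, replicate 1 had 13894 peaks with 15542 summits, and replicate 2 had 3361 peaks with 3777 summits. Median fold enrichment over input was 3.83 in replicate 1 (middle 50% of peaks, 2.89 to 5.94) and 3.34 in replicate 2 (2.83 to 4.12).

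The first comparison asked whether both replicates found LEC1-FLAG at the same places. They did for most of the strong sites. The peak at ABCI18 (AT1G03900) and ABCI19 (AT1G03905), neighbouring genes for subunits of ABC-type transporters, had the highest fold of replicate 1, at 30.4, and 8.86 in replicate 2. The peak at ABI5 (AT2G36270), a bZIP factor of abscisic acid signalling in seeds, had 22.9 and 5.21, and the peak at GSTU20 (AT1G78370), a glutathione S-transferase gene, had 14.8 and 9.43. Of the 3361 replicate 2 peaks, 3182 (94.7%) shared at least 50% of the shorter peak with a replicate 1 peak, and these met 3125 (22.5%) of the 13894 replicate 1 peaks. With 50% required of both peaks, 1686 (50.16%) were shared. With only the strongest replicate 1 peaks by q, as many as replicate 2 has, 2427 (72.2%) were shared. Random placement of the replicate 2 peaks on their chromosomes gave 177 ± 13.1 shared peaks (mean ± SD of 1000 placements, highest 220). The one-sided permutation p was 0.001, the smallest that 1000 placements can give.

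The replicate 1 peaks found again in replicate 2 were mostly strong ones. Replicate 1 peaks were divided by fold into 10 groups of equal size. In the group with the highest fold (median 11.98), 1304 of 1390 (93.8%, 95% Wilson interval 92.4 to 95.0) had a partner in replicate 2, against 17 of 1390 (1.22%, 0.765 to 1.95) in the group with the lowest fold (median 2.25). LEC2 (AT1G28300), a B3 regulator of embryo development, was one of the sites without a partner, with a replicate 1 summit at 7.43-fold on chromosome 1 at position 9900020. The strongest gene-end summits with no replicate 2 peak within 1000 bp were at CPK7 (AT5G12480), a calcium-dependent protein kinase gene, at 15.2-fold, at AT5G28040 at 12.4-fold and at LETM2 (AT1G65540) at 12.3-fold. The CPK7 summit, at position 4051244 of chromosome 5, lay inside the neighbouring gene NF-YA1. It belonged to a peak with a stronger summit of 22.55-fold at position 4052831, the strongest of all replicate 1 peaks without a partner and 26th by fold among the 13894. In the other direction 179 replicate 2 peaks had no partner. The strongest gene-end summits with no replicate 1 peak within 1000 bp were weaker, at AT5G07160 (4.32-fold), ARG1 (AT1G68370, 3.94-fold) and CID10 (AT3G49390, 3.83-fold).

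**Figure D1:**
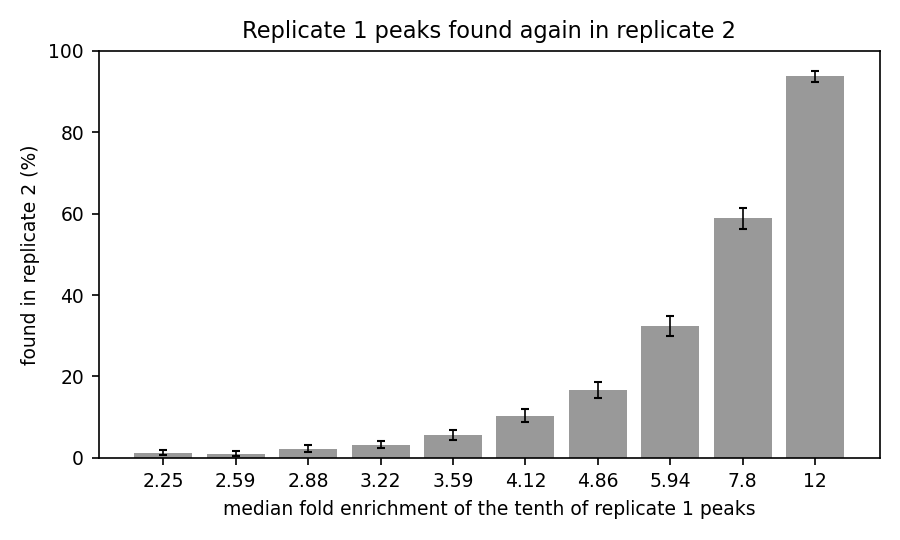
Share of replicate 1 peaks found in replicate 2 (vertical axis, percent, bars with 95% Wilson intervals) for 10 groups of equal size of the replicate 1 peaks, ordered by fold enrichment (horizontal axis, median fold of each group). The share climbs from 1.22% in the weakest group to 93.8% in the strongest.

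At the 3188 pairs of shared peaks, fold enrichment was lower in replicate 2 nearly throughout, while the order of strength was partly kept. The median fold was 8.53 in replicate 1 and 3.39 in replicate 2, and the median ratio of replicate 2 to replicate 1 was 0.412 (middle 50%, 0.327 to 0.540). Replicate 2 had the higher fold in 76 pairs (2.38%). The highest ratio (3.33) was inside FUS3 (AT3G26790), a B3 regulator of maturation, where the fold was 11.7 in replicate 1 and 39.1 in replicate 2, and the next FUS3 peak, with 10.7 and 26.3, had the third-highest (2.46). Between them lay a peak 903 bp outside AT4G32272 (2.37 and 6.09). Across pairs, Spearman's rho of the folds was 0.550 and Pearson's r of their log2 values was 0.56. Both had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. Peaks within one library are not independent replicates, and the pairs were selected for being called in both lists. Summits of paired peaks lay a median of 37 bp apart, and 61.8% lay within 50 bp.

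**Figure D2:**
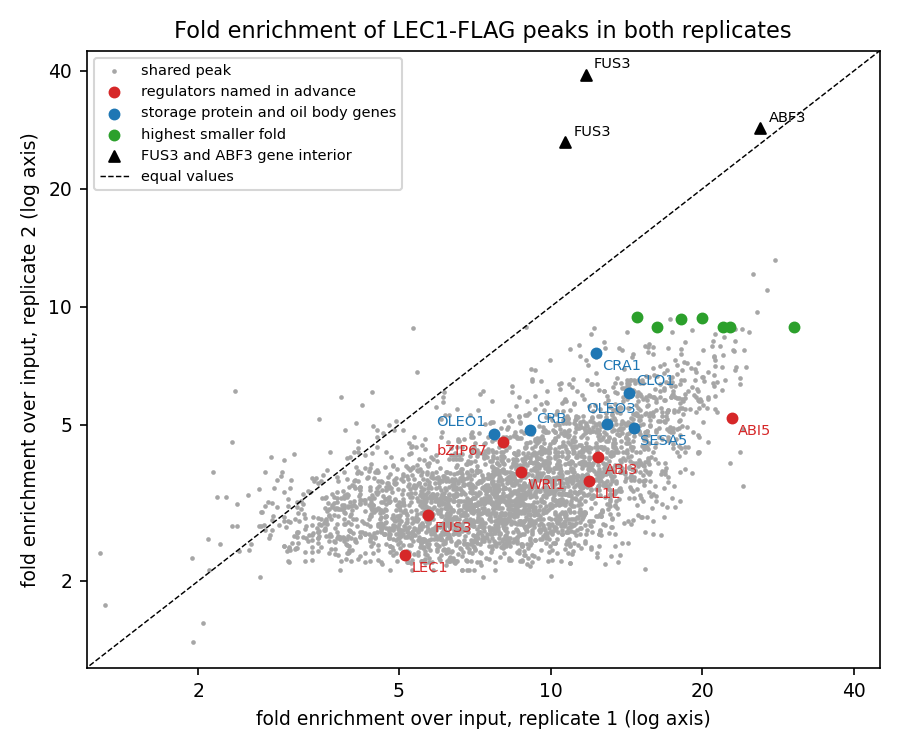
Fold enrichment over input of the 3188 shared peaks in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with gene-end summits of named genes in colour and peaks inside FUS3 and ABF3 as triangles. The dashed line marks equal values, and 76 pairs lie above it.

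The next comparison asked where in the genome LEC1-FLAG was found. Sites clustered at the ends of protein-coding genes: 1945 of the 3125 shared peaks (62.2%) had the replicate 1 summit within 1000 bp outside a gene, against 38.1% ± 0.848 by random placement (mean ± SD of 1000 placements). The one-sided permutation p was 0.001, the smallest possible. Gene interiors held 20.7% of the summits against 36.5% by chance, other gene types held 1.73% against 8.61%, and the remaining intergenic sequence held 15.3% against 16.8%. Random placement was not limited to sequence in which reads can map to 1 place, and the effect of this on the chance shares was not tested. In the full lists, 43.9% of replicate 1 summits and 43.5% of replicate 2 summits lay within 200 bp of a gene end. ABI5, ABI3 (AT3G24650) and the cruciferin gene CRA1 (AT5G44120) all had summits up to 1000 bp outside or 200 bp inside a gene end, at positions 15207731 of chromosome 2, 8996748 of chromosome 3 and 17758856 of chromosome 5. A summit in the interior of one gene and near the end of another was counted as gene end, and with the interior counted first the gene-end share was 45.5% against 20.4% by chance. The gene table used here has no strand, so the start and the end of a gene were not told apart.

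**Figure D3:**
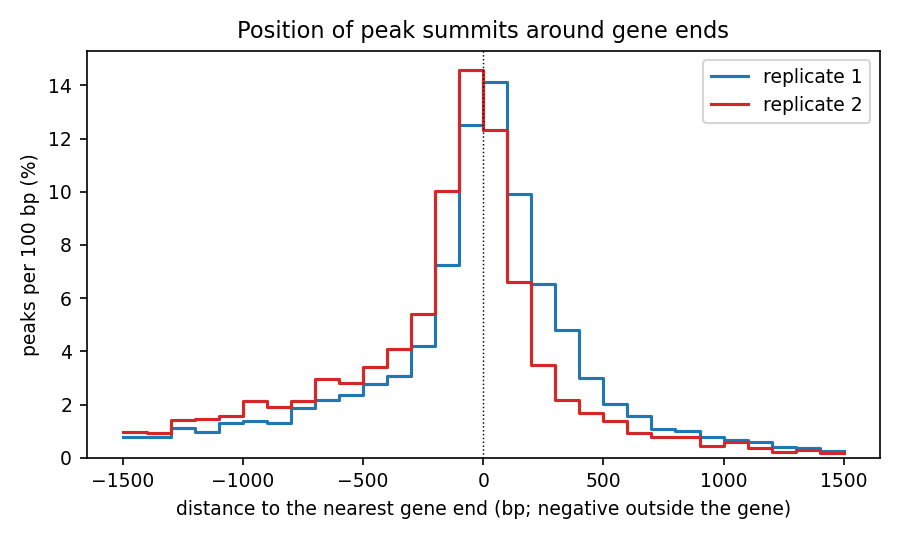
Distance of each peak's strongest summit to the nearest end of a protein-coding gene (horizontal, bp, negative outside the gene) for replicates 1 and 2, as the percent of each list's peaks per 100 bp (vertical). Both lists have their highest values in the 100 bp on either side of the gene end.

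A further comparison asked which genes LEC1-FLAG met. Regulators of seed maturation were among them in both replicates: 7 of the 8 named in advance had a summit in this gene-end window in each list. ABI5 had the highest fold of them, 22.9 in replicate 1 (95% Poisson interval of the pileup, 19.8 to 26.3) and 5.21 in replicate 2 (3.80 to 6.97). ABI3, the B3 partner of abscisic acid responses, had 12.4 (10.1 to 15.1) and 4.13 (2.87 to 5.78), and L1L (AT5G47670), the closest relative of LEC1, had 11.9 (9.69 to 14.5) and 3.59 (2.39 to 5.20). WRI1 (AT3G54320), an activator of fatty acid synthesis genes, had 8.73 (7.08 to 10.7) and 3.79 (2.61 to 5.32), and bZIP67 (AT3G44460) had 8.04 (6.21 to 10.3) and 4.52 (3.15 to 6.30). FUS3 had 5.72 (4.33 to 7.41) and 2.94 (1.93 to 4.32) at its gene end, in addition to the stronger summits in its interior.

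LEC1 itself (AT1G21970) had 5.15 (4.48 to 5.90) in replicate 1, at position 7729682 of chromosome 1, and 2.33 (1.81 to 2.95) in replicate 2. The local background there, with the 1 that MACS adds, was 40.4 fragments in replicate 1 and 28.8 in replicate 2, against medians of 8.92 and 7.52 over all nuclear summits, so the pileup of 207 fragments in replicate 1 gave no higher fold. The plants carried LEC1-FLAG under the LEC1 promoter, so signal of the native gene and of the transgene was not told apart here. LEC2 was the exception among the 8, with no summit at a gene end in replicate 2.

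In all, 3201 of 27444 protein-coding genes (11.7%) had a gene-end summit in both replicates. Replicate 1 alone gave 11634 genes and replicate 2 alone gave 3307, of which 96.8% were also in replicate 1. Independent lists of these sizes would share 1402 genes. The 10 genes with the highest smaller fold were GSTU20, AT5G01300, AT2G35470, AT4G11560, AT4G11570, AT3G53640, AT3G53650, AT1G68440, ABCI18 and ABCI19. Their folds ran from 14.8 to 30.4 in replicate 1 and from 8.86 to 9.43 in replicate 2. AT4G11560 and AT4G11570 shared 1 peak (chromosome 4, 7003842 to 7004577 in replicate 1), as did AT3G53640 and AT3G53650 (chromosome 3, 19888747 to 19889767) and ABCI18 and ABCI19 (chromosome 1, 992922 to 993965), and such a peak counted for both neighbours. With only summits within 150 bp of a summit of the other replicate counted, a filter chosen after the data were seen, 3051 genes remained. The count of target genes is bounded by the shorter list of replicate 2. Intervals on single folds cover counting error of the ChIP pileup only and leave out that of the input.

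The last comparison asked which kinds of genes LEC1-FLAG met more often than other genes, with 17 lists fixed before the data were examined. Seed storage protein genes stood highest: 10 of 13 had a gene-end summit in both replicates, against 11.6% of all other genes (odds ratio 25.3, adjusted p = 1.6e-06, Fisher's exact test). Among them were CRA1 (12.3-fold in replicate 1 and 7.62-fold in replicate 2), the albumin gene SESA5 (AT5G54740, 14.6 and 4.90) and the cruciferin gene CRB (AT1G03880, 9.10 and 4.86). The strongest CRB summits lay at different places, position 984760 of chromosome 1 in replicate 1 and 988806 in replicate 2. The summit at 988806 also counted for the neighbouring gene CRD (AT1G03890, 4.90 and 4.86), so both genes rested on the same replicate 2 peak. Oil body protein genes followed with 6 of 10 (odds ratio 11.4, adjusted p = 0.00118, Fisher's exact test). Highest by the smaller fold of both replicates were the caleosin gene CLO1 (AT4G26740, 14.3 and 6.03) and the oleosin genes OLEO3 (AT5G51210, 13.0 and 5.03) and OLEO1 (AT4G25140, 7.73 and 4.74). Of the late embryogenesis abundant and desiccation genes, which protect the drying embryo, 10 of 19 were met (odds ratio 8.44, adjusted p = 8.85e-05, Fisher's exact test), with RAB28 (AT1G03120, 18.4 and 6.52), LEA4-5 (AT5G06760, 14.9 and 6.50) and the dehydrin gene XERO1 (AT3G50980, 17.5 and 4.91). That call was lost at −log10 q of at least 10, where 3 of the 19 remained (odds ratio 7.11, adjusted p = 0.069, Fisher's exact test). All list tests were two-sided, with Benjamini-Hochberg adjustment over the 17 lists. The oil body call ended on replicate 1 alone (8 of 10 genes, adjusted p = 0.0542 by Fisher's exact test), where 42.4% of all genes were met.

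Maturation regulators were met at 9 of 21 genes (odds ratio 5.69, adjusted p = 0.00118, Fisher's exact test), the 7 above together with MYB118 (8.65 and 2.84), a regulator of endosperm maturation, and DOG1 (4.44 and 3.12), a determinant of seed dormancy. At −log10 q of at least 10, 2 of the 21 remained and the call was lost (adjusted p = 0.344, Fisher's exact test). The NF-Y list, which held subunits other than LEC1 and L1L, had 8 of 25 genes (odds ratio 3.57, adjusted p = 0.0143, Fisher's exact test), with NF-YB2 (AT5G47640, 19.9 and 6.61), NF-YA9 (AT3G20910, 14.2 and 5.06) and NF-YA1 (AT5G12840, 10.1 and 3.89) the strongest by the smaller fold of both replicates. That call held under 9 of 13 alternatives (adjusted p 0.000916 to 0.383, exact or permutation tests) and was lost with stricter peak thresholds and with the 2000 bp window. The gene-end summits of NF-YA2 (3.38 and 2.84) lay 2618 bp apart. Deeper inside that gene the replicates had summits at nearly the same place, position 1677116 of chromosome 3 (24.1-fold) in replicate 1 and 1677122 (4.87-fold) in replicate 2. With only gene-end summits within 150 bp of a summit of the other replicate, 7 of 25 genes remained (adjusted p = 0.0399, Fisher's exact test). Abscisic acid genes had 6 of 19 (odds ratio 3.50, adjusted p = 0.0376, Fisher's exact test). They included both the synthesis gene NCED9 (AT1G78390, 8.36 and 6.28) and the catabolic genes CYP707A2 (AT2G29090, 12.9 and 4.54) and CYP707A4 (AT3G19270, 7.80 and 4.25). The abscisic acid call was lost against random lists matched on intergenic length (adjusted p = 0.0574, range over its 13 alternatives 0.00023 to 0.555) and on replicate 1 alone (adjusted p = 0.337, Fisher's exact test).

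LEC1-FLAG also met photosynthesis and chlorophyll genes, at 17 of 41 (odds ratio 5.39, adjusted p = 1.06e-05, Fisher's exact test). RCA (AT2G39730), which encodes Rubisco activase, had 17.3 and 5.88, the light-harvesting gene LHCB2.2 (AT2G05070) had 15.1 and 5.00, and the photosystem I subunit gene PSAG (AT1G55670) had 9.61 and 4.32. HY5, a factor of light signalling, was also met in both replicates. At −log10 q of at least 10 only 2 of the 41 remained and the list was not called (odds ratio 1.939, adjusted p = 0.442, Fisher's exact test). The flower genes had been chosen as a control list and yet had 5 of 11 genes (odds ratio 6.32, adjusted p = 0.0143, Fisher's exact test), namely SEP2 (17.1 and 5.46), SEP3 (17.1 and 4.56), AP1 (6.82 and 3.66), SOC1 (3.03 and 4.46) and FLC (9.43 and 3.29), all MADS-box genes of flowering or flower organs. The SOC1 summits lay 4294 bp apart, so they were not 1 site found in both replicates. On replicate 1 alone the flower list was not called (5 of 11, adjusted p = 1.0, Fisher's exact test), nor with only summits within 150 bp of each other (4 of 11, without SOC1, adjusted p = 0.0562, Fisher's exact test). The flower call held under 8 of 13 alternatives. By Fisher's exact test it was also lost with the 500 bp window (adjusted p = 0.471), the 2000 bp window (0.059) and −log10 q of at least 10 (0.133).

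The other 9 lists did not pass the test. Fatty acid and triacylglycerol synthesis genes had 7 of 39 (odds ratio 1.66, adjusted p = 0.360, Fisher's exact test), with PDHE1b (AT1G30120, 13.2 and 5.32), SUS2 (AT5G49190, 7.51 and 4.66) and PDAT1 (AT5G13640, 13.2 and 4.25) the strongest by the smaller fold of both replicates. On replicate 1 alone that list had 28 of 39 genes and was called (adjusted p = 0.00111, Fisher's exact test). Gibberellin genes had 5 of 22 (adjusted p = 0.322, Fisher's exact test), with KS (AT1G79460, 9.20 and 4.19), RGL2 (AT3G03450, 7.88 and 3.65) and GA20OX2 (AT5G51810, 3.77 and 3.37). The gibberellin list was called with the whole gene in the window (7 of 22, adjusted p = 0.0382) or each summit given to its nearest gene (6 of 22, adjusted p = 0.0244), both by Fisher's exact test. The whole-gene window added RGA1 and RGL3, which had interior summits in both replicates. RGA1 lacked a gene-end summit in replicate 1, and RGL3 lacked a gene-end summit in replicate 2. Embryo patterning genes had 4 of 30, with PHB (AT2G34710, 4.23 and 5.05 at summits 4917 bp apart), TPL (AT1G15750, 9.38 and 3.79) and CUC1 (AT3G15170, 8.68 and 2.84). Brassinosteroid and PRE genes had 2 of 12, BES1 (AT1G19350, 14.1 and 4.62) and BZR1 (AT1G75080, 7.15 and 2.84). Auxin genes had 1 of 23, LAX3 (AT1G77690, 11.0 and 2.79). Seed coat genes had 2 of 19, TTG2 (AT2G37260, 11.5 and 3.25) and TT8 (AT4G09820, 4.88 and 2.69). Endosperm genes had 1 of 8, EPR1 (AT2G27380, 9.58 and 5.66). The root hair and pollen control list had 2 of 12, EXPA7 (AT1G12560, 4.08 and 3.13) and RHD2 (AT5G51060, 3.71 and 2.53), and the housekeeping control list had 1 of 7, GAPC1 (AT3G04120, 18.3 and 6.91). Intervals of these shares were wide, from 0.110% to 21.9% for auxin and from 0.361% to 57.9% for housekeeping genes (95% exact binomial). On replicate 1 alone, where 42.4% of all genes were met, the housekeeping list had 6 of 7 genes. It was not called there (odds ratio 8.16, adjusted p = 0.0886, Fisher's exact test).

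**Figure D4:**
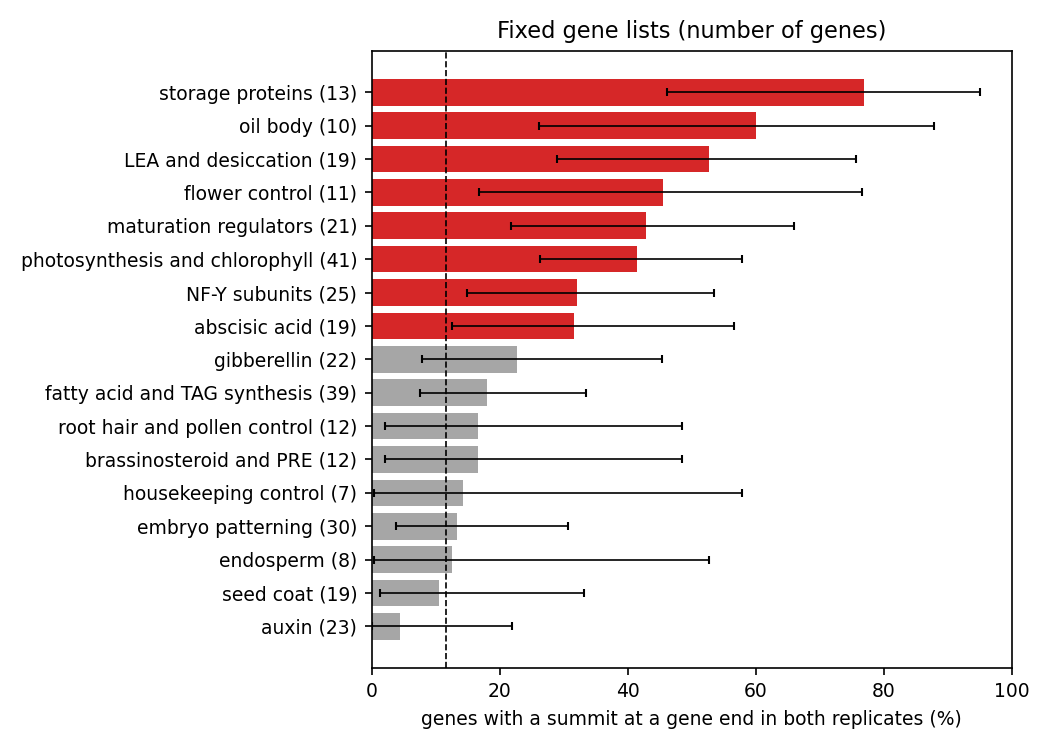
Percent of genes of each fixed list with a gene-end summit in both replicates (bars, with 95% exact binomial intervals; number of genes in brackets). The 8 lists with an adjusted p under 0.05 are red, the others grey, and the dashed line marks the 11.7% of all protein-coding genes.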

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

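The tests in this part were chosen after the result was seen. Replicate 2 had 26 peaks with 292 summits on chloroplast DNA, and replicate 1 had none, a signal outside the nuclear comparisons of the report. Their folds ran from 1.44 to 1.89 with a median of 1.72, and their pileups were near saturation, with a median of 231 fragments where 1 tag per position and strand allows 298. Binding at separate sites was argued against, because the peaks covered 75.5% of the stretch from position 9 to position 128244, and 94.9% when the longest gap, from 84203 to 110399, was left out. Removal of duplicate tags together with scaling of the deeper input library remains a candidate explanation. It allows folds up to the ratio of input to ChIP tags, 2.15, and the highest chloroplast fold was 1.888. Of the nuclear summits of replicate 2, 99.0% lay above 2.15, but this share cannot weigh on the explanation. Low folds rarely pass the q threshold at the median nuclear background of 7.52 fragments, against a median of 135 at the chloroplast summits. Why replicate 1, with a ratio of 1.70, had no such peaks was not tested, and no biological explanation other than separate binding sites was tested.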

How the results depend on the processing

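The order of priority of positions, the filter on local background, and for target genes and lists the filter on summits within 150 bp of a summit of the other replicate, were chosen after seeing the data. The other alternatives were chosen before. The rank agreement of folds kept its sign under its 6 alternatives, and the share of gene-end summits, 59.0% to 63.69% under 10 alternatives, was above all 1000 random placements of the same peaks (mean 38.07% to 38.12%). Shared peaks fell to 1686 of 3361 with reciprocal overlap, and with −log10 q of at least 5 or 10 they were 1747 of 1793 and 668 of 673, where fewer peaks entered. Moving peaks by 5 to 50 kb raised the chance overlap to 234. Target genes were 3051 when only summits within 150 bp of a summit of the other replicate counted, 1824 and 708 at −log10 q of at least 5 and 10, and 3307 to 11634 when either replicate was left out. The number of lists called was 6 to 9 under 11 of its alternatives, 8 without peaks of high local background, and 2 at −log10 q of at least 10, where few genes remained.

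Storage protein genes were called under all 13 alternatives (adjusted p 1.38e-07 to 0.00443). At −log10 q of at least 10, adjusted p was 0.344 for maturation regulators, 0.069 for desiccation, 0.442 for photosynthesis, 0.555 for abscisic acid, 0.383 for NF-Y and 0.133 for flower genes. At −log10 q of at least 5 it was 0.082 for abscisic acid and 0.171 for NF-Y, and at fold of at least 3 it was 0.144 and 0.253. With as many replicate 1 peaks as replicate 2 has, abscisic acid had 0.188, and with matched random lists 0.0574. Windows of 2000 bp gave 0.116 for NF-Y and 0.059 for flower genes, and 500 bp gave 0.471 for flower genes. That filter on summits gave 0.0562 for flower genes, where SOC1 was lost. With either replicate left out, adjusted p ran from 0.00141 to 0.0542 for oil body, 0.0437 to 0.337 for abscisic acid and 0.0174 to 1.0 for flower genes, each highest without replicate 2, where fatty acid genes were called (0.00111). Gibberellin genes were called with the whole gene in the window (0.0382) or each summit given to its nearest gene (0.0244). The genes that the whole-gene window added were RGA1 and RGL3, through summits in their interiors. The cause of the other changes was not tested, beyond the smaller number of peaks under stricter thresholds. Of the named genes, LEC1 lost its call at fold of at least 3, at −log10 q of at least 10 and without peaks of high local background, and FUS3 at fold of at least 3 and at −log10 q of at least 5 and 10. ABI3, L1L and WRI1 lost theirs at −log10 q of at least 10, where ABI5 and bZIP67 kept theirs. Over all named genes and alternatives, 60 calls were lost, 22 of them at −log10 q of at least 10, 8 were gained and 688 stayed. The alternatives for sequence elements were not run. No paired analysis was possible because no test compares ChIP with input libraries, whose pairing lies inside the authors' peak calls. Why replicate 2 had fewer peaks at a similar ChIP depth was not tested.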

Other observations

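The tests and counts in this part were chosen after the data were seen. Beyond the fixed lists, 29 gene families picked by symbol were compared with all genes, of which 11.7% were met in both replicates. None passed a Fisher's exact test after Benjamini-Hochberg adjustment (lowest adjusted p = 0.0631), and 7 had an unadjusted p under 0.05, all with a higher share. Protein kinase genes of the CIPK and CPK families had 15 of 60 (odds ratio 2.53), with CIPK12 (14.7-fold in replicate 1 and 6.38-fold in replicate 2) the strongest by the smaller fold. Trehalose synthesis genes had 9 of 30 (odds ratio 3.25), with TPPF (12.8 and 5.69) and TPPE (10.6 and 5.42). Heat shock factor genes had 7 of 21 (odds ratio 3.79), with HSFA1E (8.46 and 4.68) and HSFC1 (12.7 and 4.35), and AP2/ERF genes had 12 of 46 (odds ratio 2.68), with ERF10 (16.3 and 5.10). Cytochrome P450 genes had 18 of 234 (odds ratio 0.629).

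Of 326 nuclear microRNA genes, 14 (4.29%) had a gene-end summit in both replicates. MIR823 had the highest folds of these, 22.7 and 9.01. By the smaller fold MIR156c (8.92 and 4.79), a precursor of the microRNA that targets SPL genes, came next, and in replicate 1 it was MIR399c (13.3 and 3.89). Annotated pseudogenes were met at 32 of 3917 (0.817%), and whether reads could map to 1 place there was not tested.

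The interior of FUS3 stood apart from the other shared peaks. Its peak at position 9854211 of chromosome 3 had 39.1-fold in replicate 2 and 11.7-fold in replicate 1, the highest ratio (3.33) of 3188 pairs, and its pileup of 293 fragments was close to the ceiling of 298. Extra copies of FUS3 in the seed DNA were argued against, because the local background at that summit was 1.0 times the median. The 3 shared peaks with summits outside the gene, within 15 kb, had ratios of 0.216 to 0.515, against a median of 0.412 over all pairs. All of them lay on the same side of FUS3, so the gain ended at the gene on that side. On the other side only a replicate 1 summit 11600 bp away, without a replicate 2 partner, lay within 15 kb, so no ratio was available. FUS3 DNA added to the replicate 2 ChIP library alone, for example from a cloned or amplified copy, and a higher occupancy of FUS3 in that seed batch cannot be told apart, since both could leave the neighbours at 0.515 or below and no table here holds a second measure of occupancy.

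Few genes were covered along their length as FUS3 was. Peaks covered at least 1000 bp and 50% of the gene at 156 genes in replicate 1 and at 5 in replicate 2, and all 5 were among the 156. Among the 156, NF-YA1, NF-YA3 and HD1 (AT4G38130) had interior peaks of 22.55-fold, 18.18-fold and 13.27-fold in replicate 1 with no replicate 2 partner. The 5 were FUS3, ABF3, AT5G42050 and the DELLA genes RGA1 and RGL3, repressors of gibberellin responses. Inside ABF3, a bZIP factor of abscisic acid responses, fold reached 26.1 in replicate 1 and 28.6 in replicate 2, while the adjoining peak just outside the gene had 23.1 and 7.70 and those 10821 bp and 13574 bp outside had 3.20 and 3.05, and 7.13 and 2.24. In the interiors of the other 3 genes fold reached 8.94 and 8.88 at RGL3, 12.2 and 8.85 at RGA1 and 27.9 and 13.2 at AT5G42050. At RGA1 the signal of replicate 2 was not confined to the gene. The same peak had further summits of 5.05-fold to 6.99-fold from 8 bp to 1567 bp outside it.

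The local background at LEC1, which comes from input chromatin and includes the 1 that MACS adds, was raised in both replicates, at 4.35 to 4.52 times the median of nuclear summits in replicate 1 and 3.82 to 4.72 times in replicate 2. Extra LEC1 copies carried by the transgene are a candidate explanation: the lowest value at LEC1 was 3.82. The raised value was not confined to summits at the gene, since peaks 2725 bp (replicate 1) and 2664 bp (replicate 2) outside it had 2.17 and 2.06. On the other side peaks 4701 bp and 4705 bp outside had 0.902 and 1.0, and the nearest shared peak over 5 kb away had 1.3 and 1.06. MACS takes the local background over windows around a summit, so these values do not show how far the raised input extended. How far the extra sequence would have to extend was not tested. Sequence repeated elsewhere in the genome stays open. The names of the alignment files point to reads mapped to 1 place, which would remove reads from copies that the assembly holds, but copies missing from the assembly could raise the background. Other summits over 3 times the median were 8 in replicate 1 and 15 in replicate 2, all but 1 of them at the start of chromosome 2 or between positions 14195597 and 14202939 of chromosome 3.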
